A study of Arabidopsis thaliana with 6 samples.

How the data were processed

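RNA sequencing was used to measure transcript levels in stems of Arabidopsis thaliana, the thale cress, of the Columbia ecotype. Per the labels' protocols, wild-type (WT) plants and plants overexpressing a gene called Bnt07G011994 grew under glass, with 15 h of light and 9 h of darkness a day at 22 °C. Stems were taken at a length of about 10 cm, the stems of 1 plant making 1 sample. The labels give 3 WT and 3 overexpressor samples, 6 libraries in all, and put each sample in its group. They do not say which species or protein the overexpressed gene belongs to, whether the 3 overexpressor plants came from 1 transgenic line, at what time of day each stem was cut, or in which batch a library was made. If the samples are separate plants, as the labels' protocols give them, the p-values measure spread between plants and library preparation together.

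Per the labels' protocols, total RNA was extracted with a plant RNA column kit and libraries were made with a NEBNext Ultra RNA kit. Per the submitters' processing notes, HISAT2, a spliced aligner, was among the tools used. Its version, the genome build, the annotation, the counting program and whether counting used the strand of the reads are not given in the sources used here. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the size of the library) for 24434 genes in the 6 libraries. All 24434 identifiers matched loci of the RefSeq annotation of TAIR10.1, 23282 of them protein-coding genes and 1152 long non-coding RNAs, and no gene was at 0 in all 6 libraries. Each column was assigned to a sample by its name, and 0 columns were left over. The identifiers were all Arabidopsis loci, so the level of the transgene itself was not analysed here.

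The depth of each library was recovered from the values. FPKM multiplied by the union exonic length of each gene in TAIR10.1 stepped in whole reads for 100% of the values in each library, within a tolerance of 0.1 reads. The reads assigned to genes came to 44597288, 45265483 and 44865047 in WT replicates 1, 2 and 3, and to 45464823, 45642240 and 45092783 in overexpressor replicates 1, 2 and 3. The use of this annotation by the authors is thus inferred from the values, and coordinates below are those of TAIR10.1. In a gene with 1 kb of exons, 1 read was worth 0.0219 to 0.0224 FPKM, and a count of 3 reads, the upper limit that a count of 0 allows, 0.0657 to 0.0673 FPKM. Such limits cover counting error only.

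FPKM values are not counts, so the main test was limma (version 3.58.1, in R 4.3.3) on log2(FPKM + 1), with an intensity trend in the empirical Bayes step. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 16870 in all, two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A second count required an absolute log2 fold change of at least 1, a 2-fold change. Fold changes are on the log2(FPKM + 1) scale, overexpressor over WT, which understates the change of genes of low level. No replicate block was used. Means are given with the SD over the 3 libraries of a group. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so single genes were tested only within the limma model.

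A total of 28 gene lists with 462 members, fixed before the data were examined, covered the walls, vascular tissue and surface of stems, photosynthesis, cell division, hormones, stresses and the clock. The lists for flower and anther, seed, phloem, vessel, epidermis and photosynthesis genes served as markers of other tissues. Of the members, 6 were dropped because their symbol differed from that of the locus in the reference. The seed list had fewer than 3 members passing the filter and was not tested, which left 27 lists. They were tested with camera (limma) at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Camera with a correlation estimated from the residuals, camera on ranks and fry, a self-contained rotation test, were alternatives. Members past the gene threshold were counted over all genes tested and adjusted over the list alone.

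The rule for named genes was also fixed before the data were examined. It took the 8 genes with the largest fold change in each direction among those past the threshold whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, or all that passed if fewer. Where none passed in a direction, the 3 genes of smallest p were given as values only. For each list called by camera it took up to 4 members past the threshold, or the 2 members of highest mean FPKM where none passed. CESA4, CESA7, CESA8, NST1, NST3, MYB46 and IRX9 were always included. Other genes that are named were chosen after their values were seen, and the text says so.

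Alternatives covered the pseudocount (0.1 and 0.01 FPKM), the filter (none, or a mean of at least 5 FPKM), the scaling between libraries (median ratio, equal sums, quantile), the variance model, a replicate block, leaving out each library in turn, and the set test. After the data had been seen, sample quality weights (limma arrayWeights), voom on the recovered reads, the mean log2 level of 5 daytime clock genes (PRR9, PRR7, PRR5, GI and FKF1) as a covariate, and an estimated correlation without WT replicate 1 or with a replicate block were added. All pairs of libraries, within and across groups, were compared on their recovered reads against Poisson sampling noise. The genome was searched for copies of MRD1, AT1G27565 and 10 light-harvesting genes with blastn (BLAST+ 2.17.0), the last chosen after the data had been seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

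The fit was tested on simulated data with the means, depths, exonic lengths and spreads of these libraries, 200 genes changed by known folds, and 10 lists of 20 genes shifted by 0.5 on the log2 scale among 90 unshifted lists. Simulated genes varied independently of each other. Each gene also had the same spread in every simulated library, so no library stood apart as WT replicate 1 did in the data. The shares below therefore do not describe a fit that holds such a library. For the comparison of all 6 libraries, over 16834 genes, 47.0% of the genes changed 2-fold and 71.7% of those changed 4-fold were recovered, and 7 of 16437 unchanged genes were called. Without WT replicate 1, over 16873 genes, the shares were 68.0% and 88.0%, and 10 of 16473 unchanged genes were called. In both, camera called 10 of 10 shifted lists and 0 of 90 unshifted lists. Since the simulated genes varied independently, this does not test camera on lists whose members vary together. In the data, the estimated correlation in the called lists was 0.351 to 0.994.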

Results

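The study compared stems of Arabidopsis plants overexpressing Bnt07G011994 with WT stems, 3 plants of each, and the question the design poses is which stem transcripts differ in level between the genotypes. Each library held 44597288 to 45642240 reads assigned to genes. Between 16328 and 16853 genes per library reached 1 FPKM. The 10 genes with the highest values took 6.61 to 7.14% of the summed FPKM in each library. The plot of principal components shows the libraries. WT replicate 1 lay apart from the other 5 along the first component, which carried 74.5% of the variance, and the second component, with 12.6%, parted WT replicates 2 and 3 from the overexpressor. The Spearman correlation across genes of WT replicate 1 with each other library was 0.875 to 0.940, against 0.971 to 0.985 between WT and overexpressor libraries or within the overexpressor, and 0.997 between WT replicates 2 and 3. The spread of the WT 2 and 3 pair was 3.04 times that of sampling noise (median over genes), against 7.80 to 19.7 times in the other pairs without WT replicate 1, within and across genotypes. The 2 were counted as separate samples because the labels give them so, which their values cannot show. Fits without WT replicate 1 have only this pair as WT, so their p-values may understate the spread between WT plants.

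**Figure D1:**
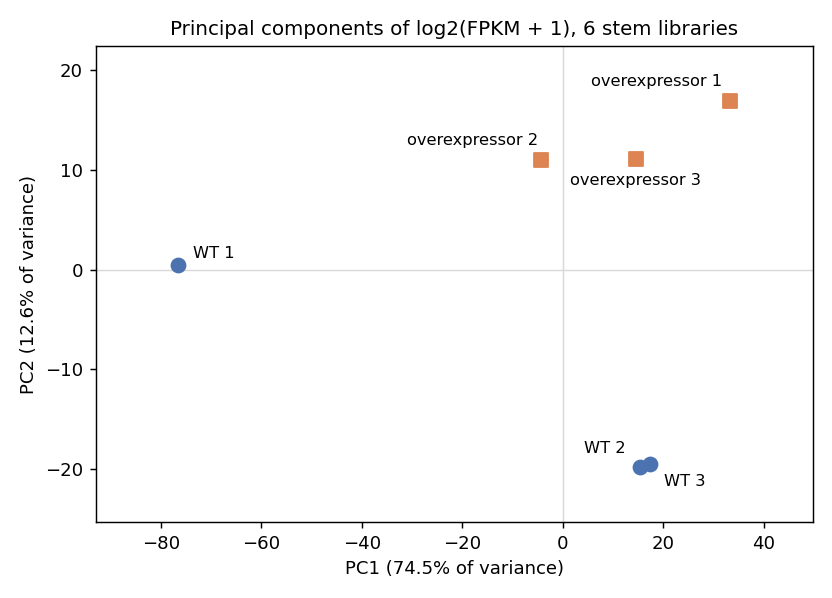
Principal components of log2(FPKM + 1) over the 16870 genes tested. Each point is 1 library (blue circles WT, orange squares overexpressor), the axes are the first component (74.5% of variance) and the second (12.6%), and WT 1 sits at -76.5 on the first axis while the other 5 libraries sit between -4.22 and 33.3.

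The clearest difference between the genotypes was in a pair of genes on chromosome 1 that were nearly silent in all 3 overexpressor stems. MRD1 (AT1G53480; chromosome 1, 19963047 to 19964712, minus strand, protein-coding) fell from 26.8 ± 1.45 FPKM in WT to 0.658 ± 0.0718 FPKM in the overexpressor (SD, n = 3 each), a log2 fold change of -4.07 (SE 0.09, limma adjusted p = 0.000148). AT1G27565 (chromosome 1, 9574550 to 9575189, plus strand, protein-coding) fell from 13.9 ± 4.06 to 0.242 ± 0.0258 FPKM (SD, n = 3 each), a log2 fold change of -3.56 (SE 0.20, limma adjusted p = 0.0170). Both differences held in each WT library against each overexpressor library, WT replicate 1 included, where MRD1 stood at 25.4 and AT1G27565 at 18.5 FPKM. These were the only genes past the threshold among the 16870 tested with limma, 0 higher and 2 lower, and both changed at least 2-fold.

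Overlaps and copies limit what the values of this pair can be assigned to. Of the 1250 bp of MRD1 exons, 922 bp overlap exons of HEI10 (AT1G53490; chromosome 1, 19963267 to 19966952, plus strand), a meiotic crossover gene, on the opposite strand. Without a statement that counting used strand, reads of the overlap cannot be given to one gene or the other. HEI10, named here after its values were seen, stood at 2.198 ± 0.0698 FPKM in WT and 0.199 ± 0.0654 FPKM in the overexpressor (SD, n = 3 each), with a limma adjusted p of 0.0702, and 0.0270 without WT replicate 1. AT1G27565 has a near-identical copy, AT1G52905 (chromosome 1, 19706047 to 19706885), whose longest matching stretch was 324 bp at 98.1% identity. The copy was at 17.41 ± 6.72 FPKM in WT and 14.5 ± 3.62 FPKM in the overexpressor (SD, n = 3 each), with a log2 fold change of -0.22 (SE 0.29) and a limma adjusted p of 0.844. The call of AT1G27565 was lost when WT replicate 2 or any 1 overexpressor library was left out, and in voom on the recovered reads, which called 1 gene. Its log2 fold changes in these fits were -3.54 to -5.69. With the replicate number as a block, both calls were lost (limma adjusted p = 0.106 for MRD1 and 0.357 for AT1G27565) at unchanged log2 fold changes.

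No gene passed the threshold in the upward direction. At an unadjusted limma p under 0.05 there were 916 genes over all 6 libraries, 341 higher and 575 lower, where chance alone gives 843.5. Without WT replicate 1 there were 1788, 762 higher and 1026 lower, against the same 843.5. The 3 values of one group all lay above or all below those of the other in 2438 genes (803 higher and 1635 lower in the overexpressor), 14.5% of those tested, where chance gives 10%. The 3 genes of smallest p in the upward direction are given as values. COR15B (AT2G42530; chromosome 2, 17708593 to 17710433), which encodes a cold-regulated chloroplast protein, stood at 13.0 ± 1.17 FPKM in WT and 30.01 ± 1.31 FPKM in the overexpressor (SD, n = 3 each; log2 fold change 1.14, limma adjusted p = 0.0702, and 0.00913 without WT replicate 1). LHB1B1 (AT2G34430; chromosome 2, 14524607 to 14525918), a light-harvesting protein of photosystem II, stood at 14.5 ± 2.44 and 66.9 ± 12.2 FPKM (SD, n = 3 each; log2 fold change 2.13, limma adjusted p = 0.0702, and 0.0143 without WT replicate 1). IDL5 (AT1G76952; chromosome 1, 28914446 to 28915102), a small peptide gene of the IDA-like family, stood at 0.322 ± 0.155 and 1.96 ± 0.127 FPKM (SD, n = 3 each; log2 fold change 1.17, limma adjusted p = 0.339). No other locus matched 50% of the LHB1B1 exons at 95% identity, and the longest other match was 806 bp at 91.4%.

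Without WT replicate 1, limma called 23 genes, 16 higher and 7 lower, of which 19 changed at least 2-fold. MRD1 and AT1G27565 were among them. The WT side of this fit is WT replicates 2 and 3 alone, which lay at only 3.04 times sampling noise. Over all 6 libraries, sample quality weights, which reweighted every library, gave 1768 calls, and the level of daytime clock genes as a covariate gave 3708. The spread of that level within groups sets the slope of the covariate. WT replicate 1 held 63.8% of it and the 3 WT libraries together 95.7%. WT replicates 2 and 3 had nearly equal levels (2.82 and 2.83), so the slope rests almost wholly on WT replicate 1 against them. Of the 16 higher genes, 10 encode light-harvesting proteins, among them CAB2 (AT1G29920), LHCB3 (AT5G54270) and LHCA1 (AT3G54890), which were named after their values were seen. Of these 10, only LHCB2.1 and LHCB2.2 had a near-identical copy by the same measure. The longest other match of CAB2 was 1155 bp at 91.7% identity, against 1314 bp of exons. Sharing of reads between such genes was not tested. CAB2 stood at 8.68 and 8.99 FPKM in WT replicates 2 and 3, at 131 to 171 FPKM in the overexpressor, and at 290 FPKM in WT replicate 1. In 12 of the 16 higher genes, WT replicate 1 lay above all 3 overexpressor libraries. The lower genes included QQS (AT3G30720), an orphan gene tied to starch and protein allocation, again named after its values were seen. QQS stood at 66.4 to 105 FPKM in the 3 WT libraries and at 5.35 to 12.1 FPKM in the overexpressor, with a limma adjusted p of 0.146 over all 6 libraries and 0.0217 without WT replicate 1.

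**Figure D2:**
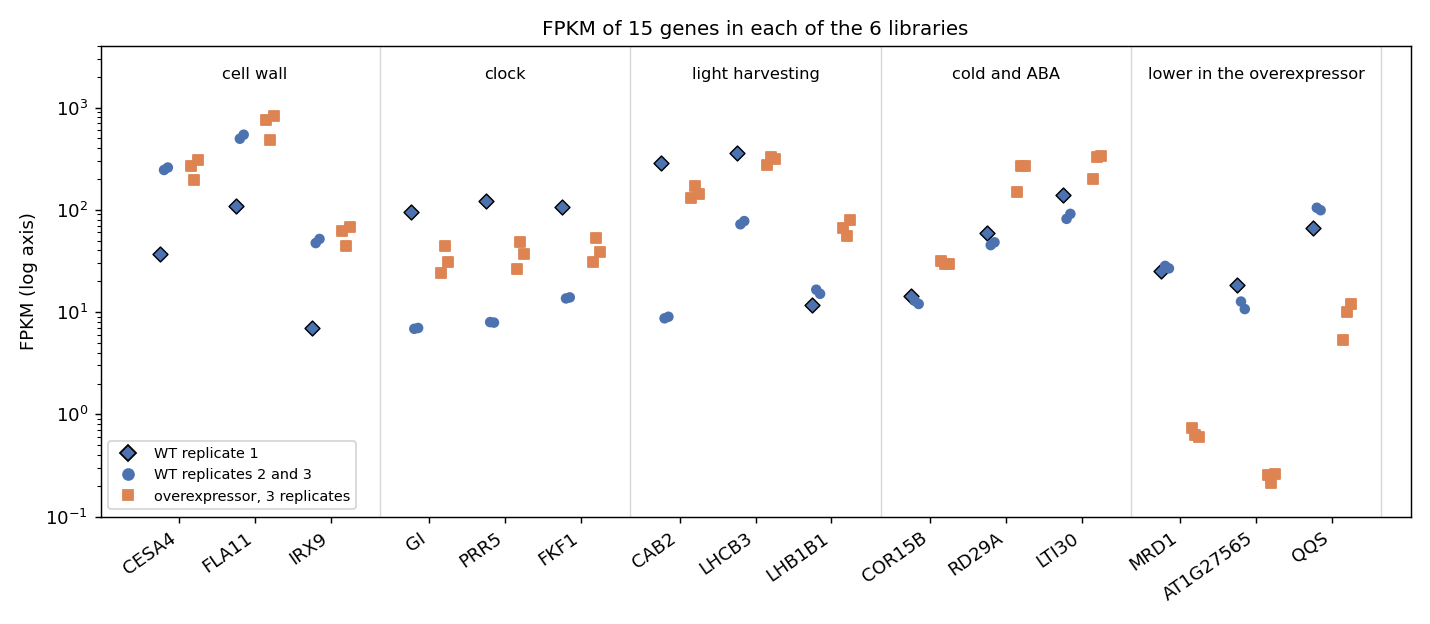
FPKM (log axis) of 15 genes in 5 groups, 1 point per library. Black-edged diamonds are WT replicate 1, circles WT replicates 2 and 3, and squares the 3 overexpressor libraries. MRD1 and AT1G27565 are below 1 FPKM in all 3 overexpressor libraries and above 10 in all 3 WT libraries, while CESA4 (37.1 FPKM) and GI (94.7 FPKM) of WT replicate 1 stand far from the other WT libraries.

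Genes of the secondary wall, the thick cellulose and xylan layer of fibres and vessels, had higher mean values in the overexpressor, and the list calls were lost without WT replicate 1. All 8 members of the secondary wall cellulose list had positive log2 fold changes (median 0.85, camera adjusted p = 0.00279), as did all 16 tested members of the xylan list (median 0.84, camera adjusted p = 1.63e-05). Of 24 tested secondary wall transcription factors, 18 were positive (median 0.29, camera adjusted p = 0.0143). The calls of all 3 lists were lost with an estimated correlation (camera adjusted p = 0.834 for each), and no member passed the threshold over all genes or adjusted over the list alone. CESA4, CESA7 and CESA8, the catalytic subunits of secondary wall cellulose synthase, stood at 180 ± 124, 180 ± 120 and 122 ± 79.0 FPKM in WT and at 256 ± 56.2, 253 ± 51.7 and 173 ± 36.2 FPKM in the overexpressor (SD, n = 3 each). In WT replicate 1 they stood at 37.1, 41.2 and 30.7 FPKM, against 163 to 259 FPKM in WT replicates 2 and 3. Without that library their log2 fold changes lay within 0.03 of 0, and the medians of the 3 lists were 0.03 for cellulose, 0.08 for xylan and -0.06 for the transcription factors (camera adjusted p = 0.610, 0.205 and 0.610).

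Other members named in these lists also had higher means in the overexpressor. FLA11, a fasciclin-like arabinogalactan protein of secondary walls, stood at 382 ± 238 FPKM in WT and 690 ± 179 in the overexpressor, and the chitinase-like CTL2 at 424 ± 249 and 591 ± 142 FPKM (SD, n = 3 each). Of the xylan genes, IRX9 stood at 35.3 ± 24.7 and 58.4 ± 12.3 FPKM, IRX15 at 95.8 ± 60.7 and 145 ± 34.4 FPKM, and PARVUS at 80.7 ± 50.9 and 112 ± 20.4 FPKM (SD, n = 3 each). Among the regulators, the NAC factors NST1 and NST3 stood at 20.9 ± 5.65 and 56.6 ± 27.8 FPKM in WT and at 31.9 ± 4.70 and 91.6 ± 24.4 FPKM in the overexpressor (SD, n = 3 each). MYB46 stood at 10.9 ± 8.08 and 19.6 ± 6.30 FPKM and KNAT7 at 82.2 ± 24.8 and 93.3 ± 14.2 FPKM (SD, n = 3 each). Limma adjusted p was 0.805 for each of these genes except KNAT7, at 0.827. The groups did not overlap for NST1. In WT replicate 1, IRX9 was at 6.91 FPKM and MYB46 at 1.58 FPKM. Without that library, log2 fold changes were 0.38 for NST1 (SE 0.12), 0.38 for FLA11, 0.29 for NST3, 0.27 for MYB46 and 0.21 for IRX9, with none called, and nearer 0 for CTL2 (0.03), IRX15 (0.12), PARVUS (0.01) and KNAT7 (-0.06). With the level of daytime clock genes as a covariate over all 6 libraries, all of these genes and the 3 CESA genes were called upward. The log2 fold change was then 1.36 for CESA4, 0.74 for NST1 and 1.62 for MYB46 (limma adjusted p = 0.00217, 0.00298 and 0.000862). The slope of that covariate rests almost wholly on WT replicate 1 against WT replicates 2 and 3, which had nearly equal levels. The 3 WT libraries held 95.7% of the spread of the clock level within groups, 63.8% of it in WT replicate 1. These calls therefore do not show higher wall genes apart from that library.

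Lignin genes and markers of vascular cells were not called over all 6 libraries. The medians were 0.19 over 20 lignin genes, 0.48 over 6 vessel markers, 0.07 over 10 cambium genes and -0.13 over 4 phloem markers (camera adjusted p = 0.261, 0.121, 0.279 and 0.300). Adjusted over the list alone, 1 phloem marker was lower in the overexpressor and no member of the other 3 lists passed. Without WT replicate 1 the lignin list was called in the other direction, with 1 of 20 members positive and a median of -0.17 (camera adjusted p = 0.00276), a call that was lost with an estimated correlation (camera adjusted p = 0.763). The same list was called upward without WT replicate 2 (0.0205), without WT replicate 3 (0.00422) and with the clock gene covariate (2.19e-05). Vessel markers were called upward in the same 3 fits (0.0205, 0.0103 and 0.00163) and had a median of -0.15 without WT replicate 1 (0.610), and cambium genes were called upward without WT replicate 3 (0.0488).

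The list calls for the primary wall and for growth were also lost without WT replicate 1. In the primary wall and expansion list 22 of 23 members were positive (median 0.38, camera adjusted p = 6.37e-07). In auxin response and transport 13 of 15 tested members were positive (median 0.51, camera adjusted p = 0.00638). In cell division 5 of 5 tested members were positive (median 0.35, camera adjusted p = 0.00482), and the rest of its 23 members fell below the 1 FPKM filter. With an estimated correlation the camera adjusted p was 0.834 for each of the 3 lists. Adjusted over the list alone 2 primary wall genes were higher with all 6 libraries and 2 without WT replicate 1, and over all genes none. The expansins EXPA4 and EXPA15, named after their values were seen, had no overlap between groups, with log2 fold changes of 1.04 and 0.53, and 0.92 and 0.42 without WT replicate 1. The cellulose-related chitinase-like CTL1 stood at 819 ± 297 FPKM in WT and 1019 ± 186 in the overexpressor, and the xyloglucan-modifying XTH24 at 549 ± 232 and 524 ± 158 FPKM (SD, n = 3 each). The auxin-response gene IAA2 stood at 112 ± 64.0 and 140 ± 50.4 FPKM and the auxin influx carrier AUX1 at 101 ± 28.6 and 106 ± 11.6 FPKM (SD, n = 3 each). The cyclin CYCD3;1 stood at 4.37 ± 1.68 and 6.09 ± 1.12 FPKM and the replication clamp PCNA2 at 3.70 ± 0.280 and 4.78 ± 0.869 FPKM (SD, n = 3 each). WT replicate 1 was below both other WT libraries in all 23, 15 and 5 tested members of these lists. Without it the medians were -0.05, -0.07 and 0.15 (camera adjusted p = 0.610, 0.759 and 0.220), while PCNA2 went only from 0.29 to 0.24.

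The wax and cuticle list, a marker of epidermis, had 18 of 20 members positive (median 0.36, camera adjusted p = 0.00183, and 0.834 with an estimated correlation). CER6, which elongates very long fatty acids, stood at 300 ± 102 FPKM in WT and 307 ± 21.9 in the overexpressor, and CER3, needed for alkane formation, at 220 ± 132 and 216 ± 22.3 FPKM (SD, n = 3 each). WT replicate 1 was below both other WT libraries in 19 of the 20 members. Without it the median was -0.07 (camera adjusted p = 0.339), and with sample quality weights the list was called downward (camera adjusted p = 0.0267).

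The photosynthesis list was called upward at the preset correlation with and without WT replicate 1, and not at an estimated one. Over all 6 libraries 28 of 30 members were positive (median 0.31, camera adjusted p = 1.44e-08), and without WT replicate 1 the median was 0.42 (camera adjusted p = 2.41e-26), with 22 members higher and 1 lower adjusted over the list alone. With an estimated correlation the camera adjusted p was 0.834 over all 6 libraries and 0.286 without WT replicate 1, and over all 6 no member passed over all genes or adjusted over the list alone. The members with the largest fold changes were light-harvesting genes. RBCS1A and RBCS3B, the members of highest level and small subunits of Rubisco, stood at 9603 ± 821 and 3845 ± 1178 FPKM in WT and at 9977 ± 1203 and 4062 ± 722 FPKM in the overexpressor (SD, n = 3 each), and LHCB3 at 170 ± 165 and 306 ± 27.2 FPKM (SD, n = 3 each). WT replicate 1 was above both other WT libraries in 25 of the 30 members.

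The clock list moved with the same library. Its median over 15 genes was 0.12 (camera adjusted p = 0.474), and without WT replicate 1 it was 0.49 (camera adjusted p = 7.07e-10, and 0.514 with an estimated correlation; 2.92e-05 with sample quality weights), with 10 members higher adjusted over the list alone. The daytime clock gene GI, named after its values were seen, stood at 94.7 FPKM in WT replicate 1, at 6.85 and 6.98 FPKM in WT replicates 2 and 3, and at 24.3 to 44.2 FPKM in the overexpressor.

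The list of genes that respond to abscisic acid, drought and cold was also called upward at the preset correlation, and not at an estimated one. Of 21 members tested 19 were positive (median 0.48, camera adjusted p = 4.11e-11), and 8 were higher adjusted over the list alone, against none over all genes. With an estimated correlation the call was lost (camera adjusted p = 0.834). COR47, a dehydrin, stood at 287 ± 10.3 FPKM in WT and 400 ± 31.1 in the overexpressor, without overlap, and RD22 at 716 ± 183 and 766 ± 175 FPKM (SD, n = 3 each; limma adjusted p = 0.778 and 0.906). When WT replicate 1 was left out, the log2 fold change of RD22 went from 0.11 to -0.12, and that of COR47 from 0.48 to 0.46. RD29A, a cold and drought marker named after its values were seen, stood at 45.1 to 59.3 FPKM in the 3 WT libraries and at 149 to 271 FPKM in the 3 overexpressor libraries (log2 fold change 2.11, limma adjusted p = 0.347). Without WT replicate 1 the list's median was 0.95 (camera adjusted p = 1.17e-13, and 0.689 with an estimated correlation). WT replicate 1 was above both other WT libraries in 18 of the 21 members.

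The flavonoid and anthocyanin list was the only one called downward, with 13 of 15 members negative (median -0.77, camera adjusted p = 0.0289, and 0.834 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The overexpressor plants varied widely in CHS and DFR. CHS, the entry enzyme of flavonoid synthesis, stood at 27.9 ± 4.97 FPKM in WT and 21.3 ± 22.7 in the overexpressor, and DFR, which leads to anthocyanins, at 28.9 ± 17.3 and 14.4 ± 17.3 FPKM (SD, n = 3 each; limma adjusted p = 0.805 for both). The call was lost without WT replicate 1 (median -0.37, camera adjusted p = 0.622). It was also lost without overexpressor replicate 3 (0.559), with no filter on low values (0.676) and with libraries rescaled to equal sums (0.0552). The regulator PAP1, named after its values were seen, stood at 14.6 ± 22.7 FPKM in WT (40.8 FPKM in WT replicate 1) and 7.52 ± 0.892 in the overexpressor (SD, n = 3 each; log2 fold change 0.42, limma adjusted p = 0.917). Without WT replicate 1 it was called higher (1.79, limma adjusted p = 0.00916), against the direction of the list.

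The sugar starvation list had 8 of 9 members positive (median 0.21, camera adjusted p = 0.00188, and 0.834 with an estimated correlation), with 2 members higher adjusted over the list alone. DIN10, of the raffinose synthase family, stood at 218 ± 158 FPKM in WT and 362 ± 239 in the overexpressor, and the F-box gene KMD4 at 89.0 ± 2.37 and 112 ± 5.002 FPKM (SD, n = 3 each), without overlap for KMD4 (limma adjusted p = 0.805 for both). DIN10 was at 36.0 FPKM in WT replicate 1 against 306 and 313 FPKM in WT replicates 2 and 3, and without that library its log2 fold change went from 1.01 to -0.02, while that of KMD4 went from 0.33 to 0.34. The median of the list was then 0.04 (camera adjusted p = 0.195).

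The other 11 lists were not called over all 6 libraries. Medians were -0.03 for gibberellin, 0.20 for brassinosteroid, 0.06 for ethylene and -0.10 for jasmonate (camera adjusted p = 0.537, 0.101, 0.590 and 0.891). They were -0.01 for salicylic acid and defence, -0.01 for glucosinolate, -0.08 for heat shock and -0.05 for rapid touch and wound response (camera adjusted p = 0.913, 0.727, 0.688 and 0.891). They were -0.09 for phosphate starvation, -0.07 for senescence and -0.16 for flower and anther markers (camera adjusted p = 0.537, 0.820 and 0.590). No member of these lists passed over all genes or adjusted over the list alone. The median was negative while the mean was positive for gibberellin (0.28), glucosinolate (0.27), jasmonate (0.11) and touch and wound response (0.10). Camera pointed up for gibberellin, glucosinolate and salicylic acid, against their medians. The touch and wound list was called downward without WT replicate 1 (median -0.11, camera adjusted p = 0.0248, and 0.514 with an estimated correlation) and with sample quality weights (0.0497). Brassinosteroid was called upward without WT replicate 2 (0.0157), WT replicate 3 (0.0129) or overexpressor replicate 2 (0.0408) and with the clock gene covariate (0.00445), and glucosinolate upward without overexpressor replicate 2 (0.000576).

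**Figure D3:**
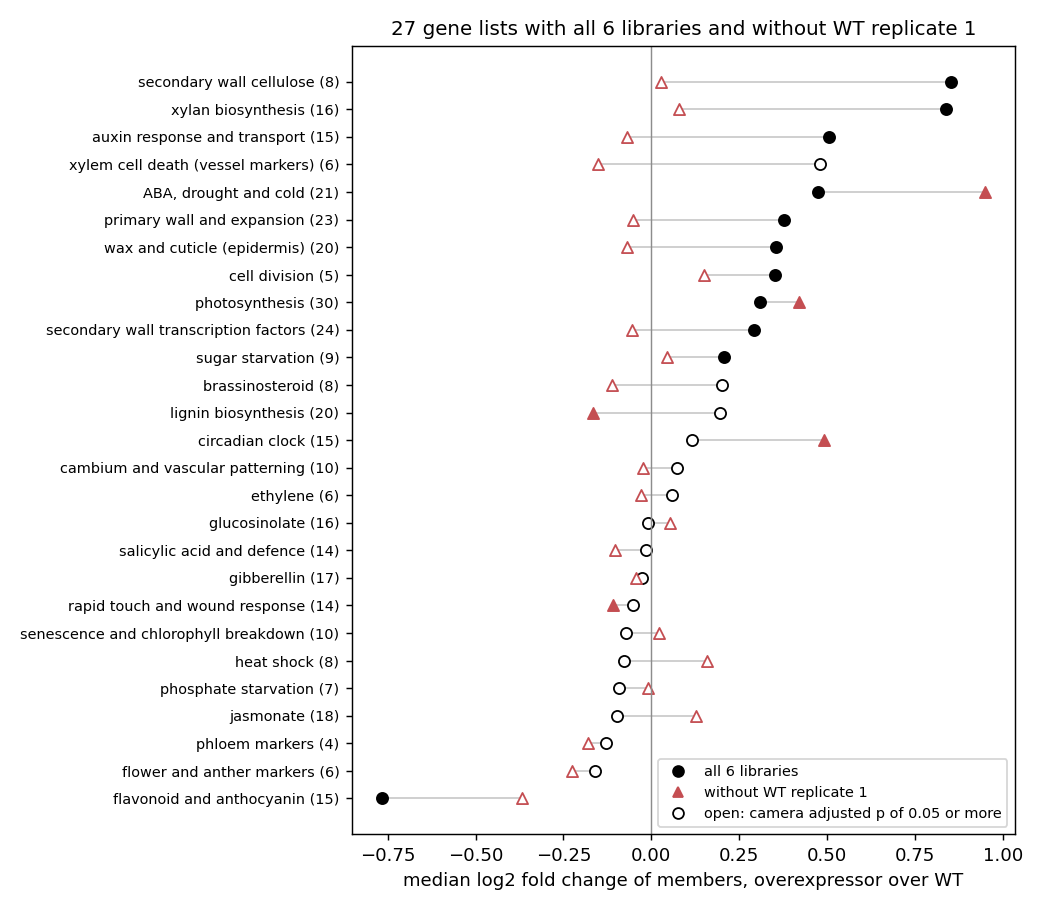
Median log2 fold change (overexpressor over WT) of the tested members of each of 27 gene lists, with the number of members in brackets. Circles use all 6 libraries and triangles leave out WT replicate 1, filled where the camera adjusted p was under 0.05. The wall lists move from 0.85 and 0.84 to 0.03 and 0.08 without WT replicate 1, while photosynthesis and the abscisic acid, drought and cold list stay above 0.

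Camera at the preset correlation called 11 of the 27 lists, 10 upward and 1 downward. With an estimated correlation, or with fry, 0 lists were called. The other splits of the 6 libraries into 3 and 3 called 11 to 18 lists at the preset correlation, so the number of list calls did not set the genotypes apart.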

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

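Sample quality weights, voom, a clock gene covariate, and an estimated correlation without WT replicate 1 or with a replicate block were chosen after the data had been seen, and the other alternatives before. The median log2 fold change of all genes was -0.04 with the values as deposited, and 0.00 to -0.05 under the other scalings. MRD1 stayed past the threshold in every alternative except the replicate block. Over the named genes, 586 of 625 values stayed on the same side of the threshold with the same sign or were uncalled in both, 7 lost and 32 gained a call, and none that was called changed sign. Over the lists, 560 of 646 did so, 62 lost a call, 16 gained one and 8 changed direction. Where a cause is not given it was not tested. Depth was alike in all 6 libraries (44597288 to 45642240 reads) and 1 read in 1 kb of exons was worth about 0.022 FPKM, so depth limits only genes far below the 1 FPKM filter.

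The count of 2 genes (limma) became 4 with no filter on low values, 1768 with sample quality weights (750 higher, 1018 lower), 3708 with the clock gene covariate (2132 higher, 1576 lower) and 1 with voom. It ranged from 1 to 23 when 1 library was left out, the highest being without WT replicate 1, which left 5 libraries. The count of 2 genes changed at least 2-fold became 160 with sample quality weights, 536 with the clock gene covariate and 1 with voom, and ranged from 1 to 19 when 1 library was left out. The sample quality weights gave WT replicate 1 a weight of 0.0837 against 0.427 to 6.94 for the others. What raised the count with the covariate was not tested. Its slope rests largely on WT replicate 1, which held 63.8% of the spread of the clock level within groups. Unlike leaving out WT replicate 1, the covariate raised the log2 fold changes of wall genes (CESA4 from 0.91 to 1.36). Besides the wall genes in the report, it gained calls for CER3, CTL1, CYCD3;1, DIN10 and IAA2, and sample quality weights for NST1, CHS and DFR. Both gained calls for COR15B, COR47, IDL5, KMD4 and LHB1B1, and no named gene called in the main fit lost its call in either. AT1G27565 lost its call without WT replicate 2, without each overexpressor library, in voom and with a replicate block, with log2 fold changes of -3.54 to -5.69. Its limma adjusted p over all its alternatives ran from 1.40e-05 to 0.357.

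The replicate numbers gave no sign of pairing the libraries. The deviations of libraries with the same number from their group means correlated at -0.60, -0.59 and 0.03 across genes. Only overexpressor replicate 3 correlated best with its own number. The deviations of WT replicates 2 and 3 were nearly alike, at 0.583 and 0.584 with overexpressor replicate 1, since WT replicate 1 dominates the WT mean. The check therefore cannot exclude pairing. With the number as a replicate block, 0 genes were called and 0 changed 2-fold, with limma adjusted p of 0.106 for MRD1 and 0.357 for AT1G27565 at unchanged log2 fold changes (-4.07 and -3.56). With the block and an estimated correlation, 0 lists were called (adjusted p = 0.789 for each of the 11).

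The count of 11 lists called by camera became 7 with sample quality weights and 0 with an estimated correlation, with fry, and with an estimated correlation without WT replicate 1. It ranged from 5 to 15 when 1 library was left out. With an estimated correlation, adjusted p was 0.834 for each of the 11 lists, and with fry it was 0.793 for photosynthesis and for abscisic acid, drought and cold, and 0.888 for the other 9. With an estimated correlation without WT replicate 1 it was 0.286 for photosynthesis, 0.689 for abscisic acid, drought and cold, and 0.906 for the other 9.

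With 1 library left out, adjusted p (camera) ranged from 2.70e-26 to 1.40e-06 for abscisic acid, drought and cold, and from 2.41e-26 to 0.000143 for photosynthesis. It ranged from 0.000173 to 0.759 for auxin, 0.000913 to 0.220 for cell division, 1.08e-05 to 0.622 for flavonoids, 5.74e-09 to 0.610 for the primary wall, 0.000143 to 0.610 for secondary wall cellulose, 0.000490 to 0.610 for secondary wall transcription factors, 0.000107 to 0.195 for sugar starvation, 5.02e-06 to 0.339 for wax and cuticle, and 1.25e-07 to 0.205 for xylan. In each of these 9 the highest value was that without WT replicate 1. There, auxin, secondary wall transcription factors and wax and cuticle also changed direction. They did so both at the preset correlation (0.759, 0.610 and 0.339) and with an estimated one (0.906 for each). The lignin list, not called over all libraries, was called downward without WT replicate 1 (0.00276), a call lost with an estimated correlation (0.763). Lists not called over all libraries also gained calls in other fits, given in the report. Auxin also lost its call without overexpressor replicate 1 (0.118), secondary wall transcription factors without overexpressor replicate 1 (0.0712) or 3 (0.143), sugar starvation without overexpressor replicate 1 (0.0584), and flavonoids without overexpressor replicate 3 (0.559).

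Under sample quality weights, camera adjusted p was 0.979 for auxin, 0.724 for cell division, 0.5996 for the primary wall, 0.0919 for secondary wall cellulose, 0.466 for secondary wall transcription factors and 0.329 for sugar starvation, and wax and cuticle was called downward (0.0267). Other lost calls were auxin with a filter of 5 FPKM (0.0779), where fewer genes were tested, flavonoids with no filter (0.676) and rescaled to equal sums (0.0552), and secondary wall transcription factors with median-ratio scaling (0.0570).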

Other observations

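The covariate, sequence copy and scaling tests below were written down before their results were seen. The tests on MRD1 in WT replicate 1, on the clock genes, on the copy of AT1G27565 and on the neighbours of MRD1 were chosen after theirs.

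Beyond the comparison of genotypes, single plants differed in whole gene groups. Relative to the mean of WT replicates 2 and 3, WT replicate 1 had median log2 differences of -2.35 over the secondary wall cellulose list, -2.28 over xylan, -2.06 over vessel markers, -1.31 over wax and cuticle and -1.28 over the primary wall. It had 1.51 over the clock list and 1.14 over flavonoids and anthocyanins. The regulator of anthocyanin synthesis PAP1 stood at 40.8 FPKM there and at 1.43 and 1.49 FPKM in the other WT plants (6.54 to 8.28 FPKM in the overexpressor), and the xyloglucan-modifying XTH4 at 8.96 against 211 and 213 FPKM. Among the overexpressor plants, DFR stood at 7.35, 34.1 and 1.66 FPKM in replicates 1, 2 and 3. The nitrate- and sugar-responsive BT2 stood at 39.0, 0.493 and 11.8 FPKM, against 0.248 to 2.99 FPKM in WT. These genes were chosen after their values were seen.

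The first pattern is the place of WT replicate 1, which over 47 cellulose, xylan and primary wall genes lay at a median of -2.03 from WT replicates 2 and 3. Median-ratio scaling left -2.06 (SE 0.17) and removing a trend on GC content and exonic length left -2.02 (SE 0.17), a trend that held 0.608% of the variance over all genes, so the tables argue against library size, composition and these biases. Each SE in this paragraph is over the 47 genes taken as independent, though they varied together. It does not measure spread between plants. MRD1 was picked from a fit with this library in the WT group, but it was also called without it (limma adjusted p = 0.000182). A mislabelled overexpressor library is argued against by MRD1, which stood at 25.4 FPKM in WT replicate 1. The daytime clock genes PRR9, PRR7, PRR5, GI and FKF1 were higher there by a median of 3.18 on the log2 scale, all 5 in that direction, consistent with a stem cut at another time of day, while a difference in age, position or health of the plant was not tested. Whether time of day also lowered the wall genes cannot be told apart from such differences, since no label gives a time: the overexpressor, higher than WT replicates 2 and 3 in the same clock genes, had a median wall difference from them of 0.026 (SE 0.04), while within it replicate 2, with the highest clock level (2.04 above WT replicates 2 and 3), had the lowest wall level (-0.32), against clock levels of 1.24 and 1.63 and wall levels of 0.21 and 0.18 in replicates 1 and 3.

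The second pattern is the upward call, at the preset correlation, of the photosynthesis list and of the abscisic acid, drought and cold list, for which collection at another time of day is a candidate explanation beside the transgene. With the mean level of the 5 clock genes as a covariate, the median of the photosynthesis list went from 0.31 to 0.24 (camera adjusted p = 3.67e-08, and 0.403 with an estimated correlation), and that of the abscisic acid, drought and cold list from 0.48 to 0.48 (0.000216, and 0.533). The bound set beforehand, a call kept with at least 50% of the median, was met but was the wrong one. The 3 WT libraries hold 95.7% of the spread of the clock level within groups, WT replicate 1 alone 63.8%. The slope therefore rests almost wholly on WT replicate 1 against the nearly equal WT replicates 2 and 3. The preset correlation also called 11 or more lists in each other split of the libraries. Among the other 5 libraries the clock level of each overexpressor plant lay 1.24 to 2.04 above WT replicates 2 and 3, so there time of day and genotype cannot be told apart. The genotype stays an open explanation that this design does not separate from collection.

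The third pattern is the near loss of MRD1 and AT1G27565. Reads shared with copies were tested first: 0 other loci matched 50% of the MRD1 exons at 95% identity (the longest match was 1060 bp at 89.9%). AT1G52905, the copy of AT1G27565, changed by -2.95 FPKM (SE 4.41). A shift of reads to it needs a rise, of about 13.7 FPKM if the 2 genes had equal exonic lengths. No conversion for length was made. A lost or silenced stretch reaching genes beyond MRD1 and HEI10 is argued against by the 4 tested neighbours of MRD1 within 10 kb. Their median log2 fold change was -0.11 (range -0.16 to 0.43). HEI10, which overlaps MRD1, was left out of that test because reads of the shared 922 bp cannot be given to one gene. That overlap is 40.9% of the HEI10 exons, and HEI10 was also lower in the overexpressor (2.198 FPKM in WT and 0.199 in the overexpressor). A lost or silenced stretch covering only MRD1 and HEI10 was therefore not tested. A difference between the seed stocks of the 2 genotypes at MRD1 and AT1G27565 may also account for their near loss, beside an effect of the transgene, and was not tested.

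The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split gave 2 genes and 2 genes of at least 2-fold, and the highest other split 0 of each, so 1 of 10 splits gave as many. For the lists, 10 of 10 splits gave as many as the real 11, and the highest other split gave 18. These calls rest on the preset correlation of 0.01: the estimated correlation was 0.351 to 0.994 in the 11 called lists, and with it 0 lists were called in each of the 10 splits, a count chosen after the data had been seen. Without WT replicate 1, the real split of the other 5 called 23 genes and 5 lists, and other splits called up to 14 genes and 5 to 13 lists, so other splits called as many lists or more with that library left out.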
